A study of Mus musculus with 6 samples.

How the data were processed

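Dorsal skin of wild-type and Tsk mice, 3 samples each, was profiled by RNA sequencing at day 40. Per the labels' protocols, shaved skin was cut out, snap frozen and homogenised, and libraries were made from total RNA after ribosomal RNA depletion with a stranded kit that marks the second strand with dUTP. Whole skin was used, so the libraries mix epidermis, hair follicles, dermis, fat and the muscle layer beneath. Per the submitters' processing notes, the tools were bcl2fastq 2.19.1.403, STAR and Partek 7.0 on the mm10 build. The gene models, strand setting and counting rule are not given in the sources used here.

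The authors deposited estimated counts per gene for 55291 genes, of which 34.8 to 37.3% per library were not whole numbers, as arises when reads are shared between genes. These expected counts were rounded to whole numbers before testing. The deposited CPM values lay within 0.472% of the count plus 0.0001 scaled to the library total, and the authors' TMM-normalised signal within 0.792% of that CPM times 1 factor per library, for every gene and library. The deposited TPM values divide by the whole gene span with introns and sum to 470308 per library, so they understate genes with long introns. Coordinates are those of mm10, and symbol, span and strand of 52904 of 55291 rows matched GENCODE M21. All 37 genes of the mitochondrial chromosome stood at 0 counts in every library, while 7 mitochondrial-like pseudogenes on chromosome 1 held 1.36 to 3.39% of counts, so mitochondrial reads were not analysed. Genes of ribosomal RNA held 6.93 ± 0.851% of counts in wild type and 4.30 ± 1.45% in Tsk (SD, n = 3 each).

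Library totals were 17561271, 18787391 and 18190596 counts in wild type and 18185272, 19219622 and 18868785 in Tsk. TMM factors averaged 0.911 ± 0.104 in wild type and 1.10 ± 0.0349 in Tsk (SD, n = 3 each). No pair of libraries agreed within sampling noise, since the smallest chi-square per degree of freedom within a group was 8.85. Counts cover sequencing depth, and reads without molecular identifiers are not independent molecules.

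Groups came from the sample labels. Counts were tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F-test, robust dispersions, TMM factors and the default expression filter (minimum count 10, minimum total 15), which left 19971 genes. Benjamini-Hochberg adjusted p-values under 0.05 were called changed, and the SE of a log2 fold change was its size divided by the square root of F. CPM values in the text are counts scaled to the TMM-adjusted library total, and all levels are mean ± SD, while all fold changes are ± SE.

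Before the data were examined, 40 gene lists with 720 symbols were fixed, of which 719 matched a row and 2 did so through RefSeq synonyms. Lists with at least 5 tested members were tested by camera (limma 3.58.1) with a preset correlation of 0.01. Camera with a correlation estimated per list and fry were alternatives. The named genes followed a rule fixed at the same time. It took Fbn1, the 12 largest rises and falls past the threshold at a mean log2 CPM of at least 1 with separated groups, up to 4 members of each list with the smallest p, the 2 most abundant members of a list with none past the threshold, and 10 genes named in advance. Some genes that this rule takes are not reported here. Alternatives fixed then were other scalings, other filters, DESeq2 1.42.0, limma-voom with and without sample weights, limma-trend on the log2 of the deposited CPM, TMM-normalised and TPM values, thinned counts and leaving out each library. A test restricted to protein-coding genes and a test with the skeletal muscle score as a covariate were added after the data were seen.

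The edgeR step was tested on simulated counts drawn from the real means, dispersions and library sizes for the Tsk against wild-type comparison. Each gene was drawn independently, so the simulation holds no correlation between genes and cannot check the list calls by camera. On 19662 simulated genes, 50.5% of genes changed 2-fold and 90.5% of genes changed 4-fold were recovered, and 6.85% of the calls were false.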

Results

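Dorsal skin RNA was sequenced in 6 mouse samples at day 40, 3 wild type and 3 carrying the tight-skin (Tsk) allele of Fbn1, the gene of fibrillin 1. Fibrillin 1 is the main protein of extracellular microfibrils, which scaffold elastic fibres in the dermis. The labels name the strain as C57BL/6 for wild type and B6.Cg-Fbn1Tsk/J for Tsk, and write the Tsk genotype as Fbn1+/-. That notation usually marks a lost copy, whereas the Tsk allele is known as an internal duplication within Fbn1, so reading these samples as heterozygous for Tsk is an assumption. Library totals ran from 17561271 to 19219622 counts, with 18179753 ± 613132 in wild type and 18757893 ± 526016 in Tsk (SD, n = 3 each). The labels number the samples but do not say that each came from a separate animal, so p-values measure the spread between these samples. The first principal component carried 44.1% of the variance and separated the groups. Log2 values of libraries correlated at 0.969 to 0.980 within a group and 0.952 to 0.968 between groups (Pearson's r across genes, which are not independent replicates).

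The comparison asked how skin of Tsk mice differed in gene expression from skin of wild-type mice. Fbn1 itself was higher in every Tsk library than in every wild-type library, at 1758 ± 301 against 302 ± 45.6 CPM (SD, n = 3 each). This was a log2 fold change of 2.54 ± 0.24 (SE, edgeR adjusted p = 0.00403). Several genes of microfibrils and elastic fibres, of secreted Wnt pathway proteins and of matrix proteases were higher in Tsk skin, while Myh3, Myh8, Ankrd1 and Slfn4 were among the genes that were lower. Of 19971 genes tested, 679 changed, 540 higher and 139 lower in Tsk, and 370 of the higher and 80 of the lower genes changed by at least 2-fold. In all 679 the 3 Tsk libraries lay on one side of the 3 wild-type libraries, which picking genes by a small p makes likely. Of all genes tested, 24.7% were separated in this way, where chance gives 10%, and 4005 had an unadjusted edgeR p under 0.05. The count rested on single libraries, at 63 (47 higher, 16 lower) without wild-type replicate 3, 328 (259 higher, 69 lower) without wild-type replicate 2, 401 (340 higher, 61 lower) without Tsk replicate 5 and 389 (324 higher, 65 lower) without Tsk replicate 6. It was 1382 without wild-type replicate 1, with a more even split of 763 higher and 619 lower, and 6 (2 higher, 4 lower) with the skeletal muscle score as a covariate, an alternative chosen after the results were seen. Other tools, filters and scalings gave 570 to 1895 genes. Of the 73 named genes past the threshold besides Fbn1, 17 passed in every one of the 6 fits that left out 1 library. With library totals alone as the scaling, 1791 genes passed and 1695 of them were higher, and the median of all genes moved up by 0.27 (log2).

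**Figure D1:**
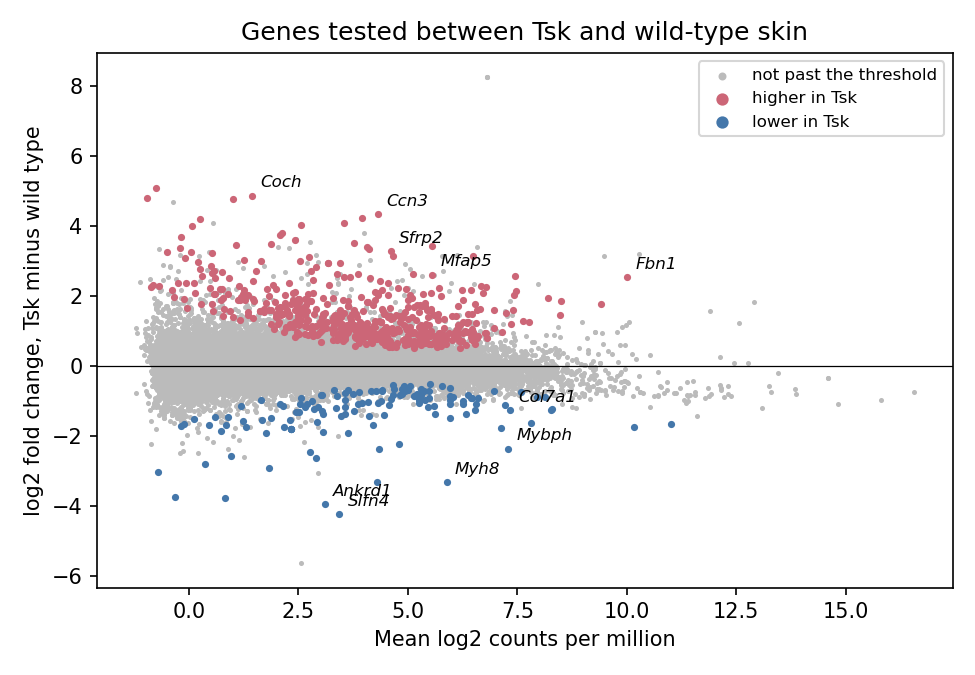
Each point is a gene tested, with its mean log2 CPM over the 6 libraries on the horizontal axis and its log2 fold change (Tsk minus wild type) on the vertical axis. The 540 genes higher in Tsk and the 139 lower are coloured, and Fbn1 stands at a log2 fold change of 2.54.

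Fbn1 lies on chromosome 2 from 125300594 to 125507993 on the minus strand of the mm10 genome build. Its 3 wild-type libraries held 4684, 5420 and 4765 counts and its 3 Tsk libraries 27971, 43910 and 37855 counts. The gene-level count sums both alleles and does not tell the Tsk transcript from the normal one.

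The 12 largest rises among genes at a mean log2 CPM of at least 1 were led by Coch, which encodes the matrix protein cochlin, at 4.86 ± 0.42 (log2 fold change ± SE). Ccn3, a secreted matricellular protein, rose by 4.33 ± 0.20, from 1.87 ± 0.165 to 37.7 ± 7.59 CPM, and had the smallest adjusted p of all genes (edgeR, 0.000126). Dact2, an intracellular regulator of Wnt and TGF-beta signalling, rose by 4.09 ± 0.31, and the natriuretic peptide protease Corin by 3.49 ± 0.34. Retnla, a secreted protein of alternatively activated macrophages and fat, rose by 3.44 ± 0.36. The protease Adamts8 rose by 3.59 ± 0.60, the cell adhesion protein Pcdh20 by 3.78 ± 0.52 and the inner root sheath keratin Krt71 by 3.74 ± 0.74. Pinlyp (4.21 ± 0.82), the secreted carbonic anhydrase Car6 (4.03 ± 0.69), the cornified envelope gene Sprr4 (3.45 ± 0.63) and Lep (3.50 ± 0.69), which encodes leptin, completed the set. Wild-type counts were 5, 2 and 1 for Coch, 10, 2 and 4 for Sprr4, 11, 5 and 12 for Corin, 3, 21 and 14 for Adamts8, 20, 3 and 5 for Pcdh20 and 23, 3 and 7 for Car6, so these folds rest on few counts. Of the 6 fits that left out 1 library, Krt71 and Pinlyp passed in 1, Sprr4 in 2, Car6 and Lep in 3, Adamts8 in 4 and Pcdh20 in 5, and the other 5 of these rises in all 6.

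The microfibril and elastic fibre list had 11 of 24 members higher and none lower, and 16 higher when adjusted over the list alone, with a median log2 fold change of 0.96 (camera adjusted p = 3.27e-24). Microfibril genes had adjusted p = 0.326 with an estimated correlation. Besides Fbn1, the microfibril-associated genes Mfap5 and Mfap2 rose by 2.61 ± 0.23 and 1.94 ± 0.25. The elastic fibre proteins Emilin2 and Efemp1 rose by 2.23 ± 0.23 and 2.20 ± 0.19, and Eln, the gene of elastin, rose by 1.60 ± 0.27 from 83.8 ± 29.2 to 254 ± 45.3 CPM (edgeR adjusted p = 0.0195). The second fibrillin gene, Fbn2, rose by 1.35 ± 0.27, from 5.56 ± 1.90 to 14.1 ± 3.53 CPM. With 1 library left out, Fbn2 passed in 1 of 6 fits, Eln in 4, Mfap2 in 5 and the other 3 named here besides Fbn1 in all 6.

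**Figure D2:**
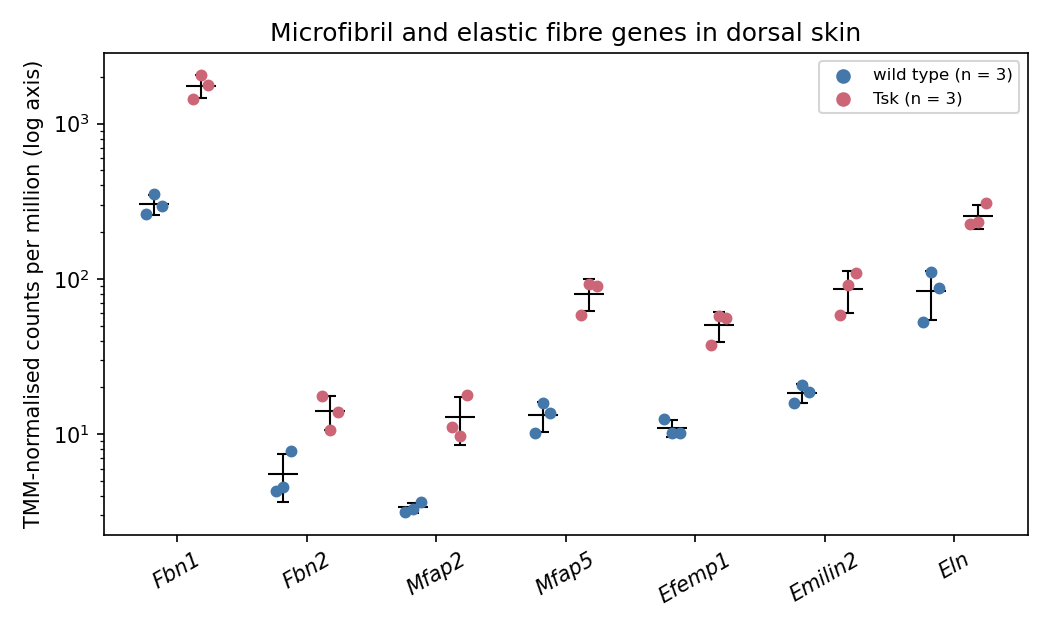
Points are TMM-normalised CPM of single libraries on a log axis for 7 genes of the microfibril and elastic fibre list, wild type in blue and Tsk in red, with bars for the mean and SD of 3 libraries. Every Tsk library of Fbn1 lies above every wild-type library, with means of 1758 and 302 CPM.

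In the list of fibrillar collagens and their processing, 3 of 29 members rose, and 15 did when adjusted over the list alone, with a median of 0.76 (camera adjusted p = 8.34e-11). Collagen genes had adjusted p = 0.492 with an estimated correlation. Col14a1, a collagen on the surface of fibrils, rose by 2.14 ± 0.30, the procollagen protease Bmp1 by 1.23 ± 0.19 and Crtap, part of the collagen prolyl 3-hydroxylation complex, by 0.94 ± 0.13, and each passed in 5 of the 6 fits with 1 library left out. The major fibrillar collagens did not pass, with log2 fold changes of 1.83 ± 0.44 for Col1a1 (edgeR adjusted p = 0.0614) and 1.24 ± 0.38 for Col3a1 (edgeR adjusted p = 0.116). Collagen list genes took 1.05 ± 0.220% of counts in wild type and 3.41 ± 1.66% in Tsk, where replicate 6 held 5.33%.

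Among matrix proteases and inhibitors, 5 of 20 members rose, and 9 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 5.37e-06). Protease genes had adjusted p = 0.492 with an estimated correlation. Adamts5, a protease of proteoglycans, rose by 1.71 ± 0.17, Mmp23 by 2.10 ± 0.30, Mmp14 by 1.26 ± 0.26 and the inhibitor Timp2 by 1.27 ± 0.26. The basement membrane list had 3 of 20 members higher and 1 lower, 4 and 1 when adjusted over the list alone (camera adjusted p = 0.296). Nid1, Lama4 and Lamb1 rose by 1.45 ± 0.32, 1.16 ± 0.17 and 1.05 ± 0.19, while Col7a1, which forms the anchoring fibrils below the epidermis, fell by 1.27 ± 0.21 on the log2 scale, from 227 ± 32.5 to 94.4 ± 22.7 CPM. Mmp14 and Timp2 passed in 1 of the 6 fits with 1 library left out, Nid1 and Lamb1 in 3, Col7a1 in 4, Mmp23 and Lama4 in 5 and Adamts5 in all 6.

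Of 22 tested members of the Wnt list, 6 rose, and 13 did when adjusted over the list alone, with a median of 0.76 (camera adjusted p = 2.14e-10). Wnt genes had adjusted p = 0.326 with an estimated correlation. The ligands Wnt2 and Wnt10b rose by 2.99 ± 0.45 and 2.82 ± 0.25, and the secreted modulators Sfrp2 and Dkk2 by 3.27 ± 0.32 and 1.63 ± 0.25. The list holds ligands and inhibitors as well as response genes, and Sfrp2 and Dkk2 are known to bind Wnt ligands or their receptors. In the TGF-beta list, 3 of 22 members rose, and 6 did when adjusted over the list alone, with a median of 0.31 (camera adjusted p = 0.000990). TGF-beta genes had adjusted p = 0.492 with an estimated correlation. Fibronectin (Fn1) rose by 1.76 ± 0.27, Id3 by 1.08 ± 0.16 and the receptor Tgfbr2 by 0.94 ± 0.20. The ligand gene Tgfb1 stood at 0.47 ± 0.19 (edgeR adjusted p = 0.207) and Ccn2, a TGF-beta and mechanical response gene, at 0.21 ± 0.18 (edgeR adjusted p = 0.584). In the list of myofibroblast and fibroblast activation, Sfrp2 and Thy1 (0.72 ± 0.15) were the 2 of 18 members that rose, and 4 did when adjusted over the list alone (camera adjusted p = 8.38e-05). Myofibroblast genes had adjusted p = 0.492 with an estimated correlation. Thy1 passed in 1 of the 6 fits with 1 library left out, Tgfbr2 in 2, Wnt2, Dkk2, Fn1 and Id3 in 5, and Wnt10b and Sfrp2 in all 6. Acta2, the smooth muscle actin of myofibroblasts, stood at 0.34 ± 0.18 (edgeR adjusted p = 0.342). The tendon and cartilage list did not pass (camera adjusted p = 0.135), with 0 of 14 members changed and 1 higher when adjusted over the list alone. Its most abundant members Bgn and Cilp stood at 0.42 ± 0.26 and -0.60 ± 0.33.

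The adipocyte list had a median of 2.16, with 3 of 22 members higher and 17 when adjusted over the list alone (camera adjusted p = 1.35e-09). Adipocyte genes had adjusted p = 0.492 with an estimated correlation. Lep, the complement factor D gene Cfd (2.56 ± 0.54) and Cebpa (1.43 ± 0.29) rose, and Adipoq, the gene of adiponectin, stood at 3.13 ± 0.76 without passing (edgeR adjusted p = 0.0748). Without Tsk replicate 5 the median was 1.08, Cfd stood at 1.60 and Adipoq passed at 1.72, as it did at 3.57 without Tsk replicate 6. The list's share of counts was 0.455, 1.06 and 0.403% in the 3 Tsk libraries and 0.365, 0.447 and 0.419% in the 3 wild-type libraries, so Tsk replicate 5 stood apart. Car3, at 3090 ± 593 CPM in wild type and 2250 ± 359 in Tsk, weighs heavily in that share. The mean log2 CPM of the list's members was 5.90, 7.63 and 5.38 in Tsk against 4.62, 4.89 and 4.57 in wild type, which separated the groups. Fatty acid and triglyceride synthesis genes had 1 of 18 members higher, Scd2 at 0.88 ± 0.14, also 1 when adjusted over the list alone (camera adjusted p = 0.000377). Fatty acid genes had adjusted p = 0.504 with an estimated correlation. Their median was 0.80, and 0.39 without Tsk replicate 5. Cebpa passed in 2 of the 6 fits with 1 library left out, Lep and Cfd in 3 and Scd2 in 4. Cholesterol synthesis genes had 0 of 20 members changed, and 0 when adjusted over the list alone (camera adjusted p = 0.0145). Cholesterol genes had adjusted p = 0.514 with an estimated correlation, and Hmgcs1 stood at 0.17 ± 0.17. Thermogenic adipocyte genes did not pass (0 of 8 members, camera adjusted p = 0.686), with Cox7a1 at -0.35 ± 0.36 and Cox8b at -0.26 ± 0.32.

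Skeletal muscle genes took 23.2 ± 4.45% of counts in wild type and 16.7 ± 1.16% in Tsk, with wild-type replicate 1 at 18.1% and Tsk replicate 4 at 17.9%. No member of the 20 passed over all genes, and 14 were lower and 1 higher when adjusted over the list alone, with a median of -0.81 (camera adjusted p = 4.11e-09). Skeletal muscle genes had adjusted p = 0.492 with an estimated correlation. The fast myosin gene Myh4 stood at -1.09 ± 0.36 (edgeR adjusted p = 0.136) and titin (Ttn), which alone took 10.7 ± 1.97% of wild-type counts, at -0.74 ± 0.41. Among the 12 largest falls, the embryonic myosin Myh3 fell by 3.30 ± 0.35 on the log2 scale and the perinatal myosin Myh8 fell by 3.31 ± 0.45. The embryonic light chain Myl4 fell by 2.64 ± 0.32, and the stress-induced gene Ankrd1 fell by 3.96 ± 0.51. Mybph, Rrad, the myogenic regulator Myog and the myoblast fusion gene Mymk changed by -2.36 ± 0.33, -2.47 ± 0.32, -1.92 ± 0.22 and -1.91 ± 0.39. Slfn4, an interferon-responsive myeloid gene, fell by 4.24 ± 0.57, the metallothionein Mt3 fell by 2.91 ± 0.44 and Enho fell by 1.90 ± 0.32. Rnu3b1, a small nucleolar RNA at -1.79 ± 0.26, is 1 of 4 copies with identical counts, so its reads cannot be assigned to a copy. Of the 6 fits that left out 1 library, Mymk and Enho passed in 2, Mt3 in 4 and Rrad, Mybph and Rnu3b1 in 5, and the other 6 of these falls in all 6.

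**Figure D3:**
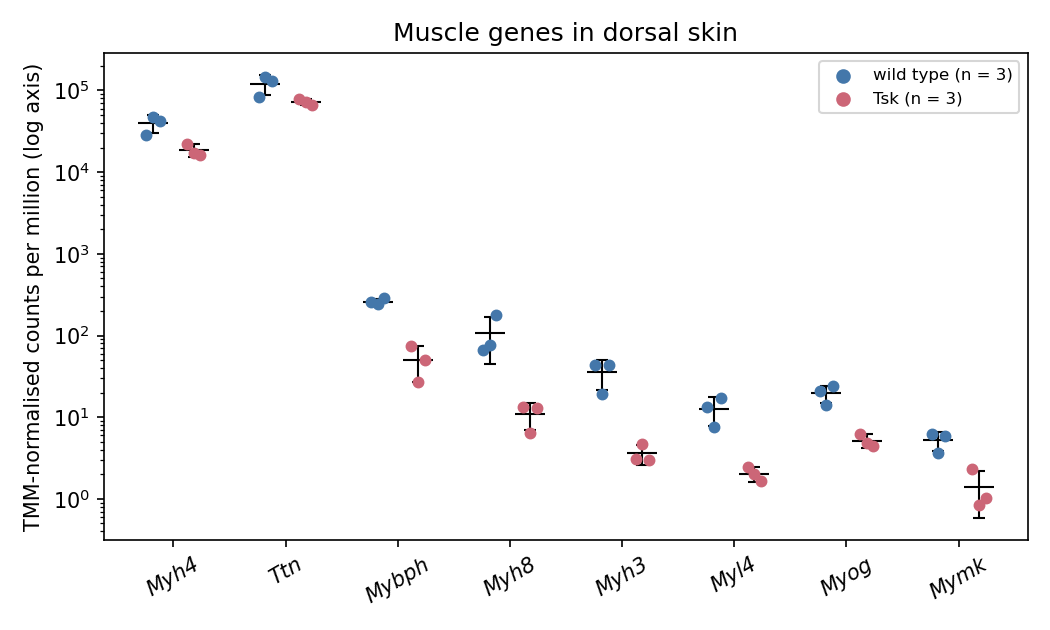
Points are TMM-normalised CPM of single libraries on a log axis for 8 muscle genes, wild type in blue and Tsk in red, with bars for the mean and SD of 3 libraries. Myh4 and Ttn did not pass the test, and the other 6 genes fell, Myh3 from 35.7 to 3.61 CPM.

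The endothelial list had 4 of 20 members higher, 13 when adjusted over the list alone, with a median of 0.77 and all 20 members above 0 (camera adjusted p = 3.92e-11). Endothelial genes had adjusted p = 0.492 with an estimated correlation. Lyve1 rose by 2.22 ± 0.46, Tek by 1.29 ± 0.21, Plvap by 1.16 ± 0.15 and Vwf by 0.99 ± 0.16. In Tsk replicates 4, 5 and 6 Lyve1 stood at 22.2, 31.4 and 80.7 CPM. The smooth muscle and pericyte list had 2 of 14 members higher, Mylk (0.87 ± 0.13) and Myh11 (0.79 ± 0.16), and 6 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.00804). Smooth muscle genes had adjusted p = 0.492 with an estimated correlation. The nerve and Schwann cell list had 2 of 15 members higher, Scn7a (1.46 ± 0.29) and Pmp22 (0.93 ± 0.19), and 8 when adjusted over the list alone (camera adjusted p = 8.72e-06). Schwann cell genes had adjusted p = 0.492 with an estimated correlation. Myh11 passed in 1 of the 6 fits with 1 library left out, Scn7a and Pmp22 in 2, Lyve1 in 3 and Tek, Plvap, Vwf and Mylk in 5.

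In the epidermis list, 4 of 20 members rose, and 6 did when adjusted over the list alone (camera adjusted p = 0.000221). Epidermis genes had adjusted p = 0.504 with an estimated correlation. The cornified envelope protein Lor rose by 1.78 ± 0.22, the corneodesmosome genes Cdsn and Dsc1 by 1.48 ± 0.24 and 1.38 ± 0.23, and the cross-linking enzyme Tgm1 by 1.13 ± 0.21. The list had 6 members below 0, none of which passed, the basal cell genes Krt5 (-0.60 ± 0.31), Krt14 (-0.61 ± 0.38), Itgb4 (-0.47 ± 0.20) and Itga6 (-0.26 ± 0.21) and the differentiation genes Ivl (-0.29 ± 0.22) and Krt1 (-0.23 ± 0.29), named after their values were seen. The list of stress and wound epidermis did not pass (camera adjusted p = 0.934), with Sprr1a (1.81 ± 0.38) the 1 of 12 members that rose, 2 higher and 2 lower when adjusted over the list alone, and a median of 0.12 against a mean of -0.38. That median was 0.32 without wild-type replicate 3 and -0.22 without Tsk replicate 4. Inner root sheath and hair matrix genes had 4 of 17 members higher, and 5 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00295). Inner root sheath genes had adjusted p = 0.326 with an estimated correlation. Their median was 0.24 against a mean of 0.87, with 5 of the 17 members below 0. Beside Krt71, the keratins Krt25 and Krt27 rose by 4.77 ± 0.74 and 2.58 ± 0.51 and the transcription factor Dlx3 by 1.86 ± 0.29. The keratin folds rest on few wild-type counts, which were 2, 4 and 0 for Krt25, 4, 6 and 5 for Krt27 and 24, 4 and 0 for Krt71. Across alternatives Krt25 ran from 0.63 to 9.41 and Krt71 from 0.92 to 9.39, and Krt71 stood at 5.83 without wild-type replicate 1. Sprr1a and Krt71 passed in 1 of the 6 fits with 1 library left out, Krt27 in 2, Dsc1 and Tgm1 in 4 and Lor, Cdsn, Krt25 and Dlx3 in 5. The hair shaft list had 0 of 16 members changed and 5 higher when adjusted over the list alone (camera adjusted p = 0.00180). Hair shaft genes had adjusted p = 0.492 with an estimated correlation, with Selenbp1 at 0.53 ± 0.22 and Krt84 at -0.30 ± 0.65. The hair follicle stem cell and dermal papilla list did not pass (camera adjusted p = 0.205). Corin and Cd34 (0.94 ± 0.16) rose and Krt24 fell by 1.09 ± 0.22, and these calls held in 6, 3 and 0 of the 6 fits with 1 library left out. The list had 3 higher and 1 lower of 18 when adjusted over the list alone. The sebaceous gland list had 0 of 16 members changed, and 0 when adjusted over the list alone (camera adjusted p = 0.0478). Sebaceous genes had adjusted p = 0.574 with an estimated correlation, with Scd1 at 3.19 ± 0.95, which was 1.21 without Tsk replicate 5, and Krt79 at 0.62 ± 0.42, which was 0.23 without wild-type replicate 2 and 0.96 without wild-type replicate 1. The melanocyte list did not pass (0 of 9 members, 1 higher when adjusted over the list alone, camera adjusted p = 0.0912), with Dct at 0.98 ± 0.24 and Mitf at 0.024 ± 0.14.

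Among immune lists, complement had 3 of 16 members higher and 10 when adjusted over the list alone, with a median of 0.95 (camera adjusted p = 7.12e-06). Complement genes had adjusted p = 0.492 with an estimated correlation. The complement median was 0.49 without Tsk replicate 6. C4b rose by 2.03 ± 0.28 and C2 by 1.12 ± 0.21, calls that held in 5 and 2 of the 6 fits with 1 library left out. Macrophage and dendritic cell markers had 0 of 21 members changed and 7 higher when adjusted over the list alone (camera adjusted p = 6.69e-05). Macrophage genes had adjusted p = 0.498 with an estimated correlation, with Cd74 at 0.93 ± 0.25 and Lyz2 at 0.84 ± 0.34. Mast cell markers had 0 of 9 members changed and 5 higher when adjusted over the list alone (camera adjusted p = 0.00601). Mast cell genes had adjusted p = 0.492 with an estimated correlation, with Kit at 1.01 ± 0.27 and Gata2 at 0.49 ± 0.36. Of 13 chemokines and cytokines, Cxcl12 rose by 0.99 ± 0.14 (past the threshold in 5 of those 6 fits), also the 1 when adjusted over the list alone (camera adjusted p = 0.465). The interferon response list had 0 of 20 members changed, and 0 when adjusted over the list alone, with a median of -0.54 (camera adjusted p = 0.00127). Without wild-type replicate 1 that median was -0.12. Interferon genes had adjusted p = 0.559 with an estimated correlation, with Ifi27 at 0.31 ± 0.33. The T and NK cell list did not pass (0 of 13 members, camera adjusted p = 0.465), with Cd3d at -0.17 ± 0.24 and Trdc at 0.34 ± 0.27. B and plasma cell and neutrophil markers had 3 tested members each, too few for a list test, with Ighm at -0.20 ± 0.20, Ms4a1 at -0.34 ± 0.24, Cxcr2 at -0.28 ± 0.19 and Csf3r at -0.69 ± 0.47.

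Cell proliferation genes had 0 of 22 members changed, and 0 when adjusted over the list alone, with a median of -0.43 (camera adjusted p = 0.00289). That median was -0.17 without wild-type replicate 1 and -0.65 without wild-type replicate 2. Proliferation genes had adjusted p = 0.574 with an estimated correlation, with Mki67 at -0.52 ± 0.26 and Top2a at -0.32 ± 0.25. Glycolysis and hypoxia genes had 0 of 20 members changed and 1 higher when adjusted over the list alone, with a median of -0.53 (camera adjusted p = 0.00387). Glycolysis genes had adjusted p = 0.493 with an estimated correlation, with the muscle-abundant enzymes Aldoa and Pkm at -0.87 ± 0.30 and -0.85 ± 0.26. No member passed in the lists of nuclear oxidative phosphorylation (0 of 20, camera adjusted p = 0.0742), immediate early and heat shock (0 of 16, camera adjusted p = 0.288), unfolded protein response (0 of 16, camera adjusted p = 0.465), circadian clock (0 of 17, camera adjusted p = 0.713), sex-linked genes (0 of 5, camera adjusted p = 0.0866) and erythrocyte genes (0 of 5, camera adjusted p = 0.135). Their most abundant members were Atp5b (-0.23 ± 0.30) and Atp5a1 (-0.21 ± 0.30), Nr4a1 (-0.97 ± 0.37) and Hspa1b (-0.033 ± 0.17), Calr (0.023 ± 0.14) and Hsp90b1 (0.11 ± 0.15), Tef (-0.13 ± 0.16) and Per1 (0.12 ± 0.14), Ddx3y (-0.31 ± 0.15) and Kdm5d (-0.13 ± 0.13), and Hba-a2 (1.04 ± 0.49) and Hbb-bs (0.81 ± 0.65). Mitochondrially encoded genes had 0 of 13 members tested. The Y-linked gene Ddx3y was present in all 6 libraries, from 50.2 to 80.9 CPM.

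**Figure D4:**
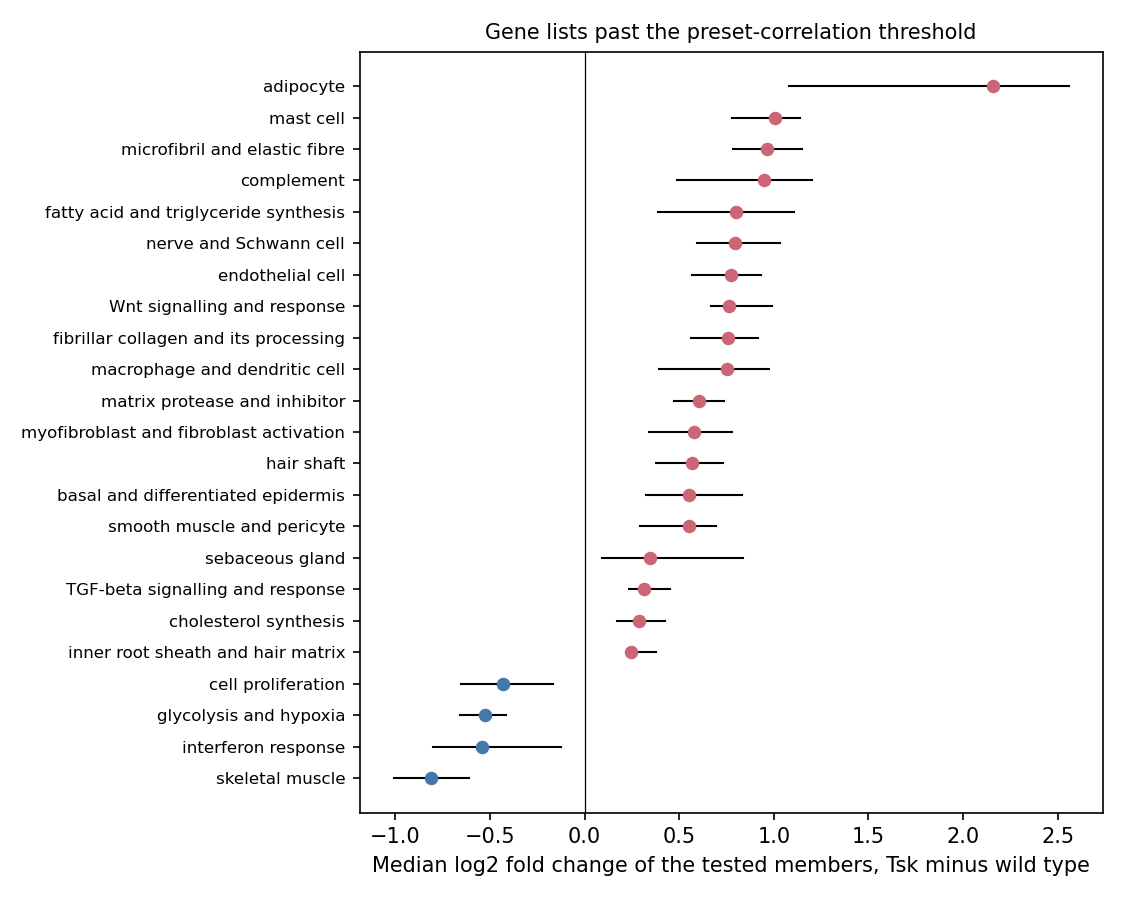
Points are the median log2 fold change (Tsk minus wild type) of the tested members of each of the 23 lists past the threshold with a preset correlation of 0.01, and lines run from the lowest to the highest median when 1 library was left out. The adipocyte list has the highest median, 2.16, and skeletal muscle the lowest, -0.81, and 0 of the lists passed with an estimated correlation.

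Of 37 lists tested by camera with the preset correlation, 23 passed, 19 higher and 4 lower in Tsk. With an estimated correlation 0 passed (3 at an unadjusted p under 0.05) and 0 passed by fry (10 at an unadjusted p under 0.05), so each list call rests on the preset correlation. Fry's mixed test, which asks whether members change in either direction, passed for 17 of the 37 lists. Leaving out 1 library ended the calls of the smooth muscle, proliferation, mast cell and interferon lists (wild-type replicate 1), the cholesterol list (wild-type replicate 2, Tsk replicates 4 and 5), the sebaceous list (wild-type replicates 2 and 3, Tsk replicate 5), the epidermis list (Tsk replicate 4) and the glycolysis list (Tsk replicate 6). The lower share of skeletal muscle counts in Tsk libraries ran alongside all of these list values. So did a lower share of ribosomal RNA counts, at 7.81, 6.87 and 6.11% in wild type and 5.46, 2.68 and 4.76% in Tsk, with no overlap between the groups.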

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

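The tests restricted to protein-coding genes and those with the skeletal muscle score as a covariate were chosen after the results were seen. No paired analysis was possible because the groups share no replicate numbers. Fbn1 passed and stayed higher in Tsk under every alternative run, from 2.32 to 2.83 (log2). The 679 genes (540 higher, 139 lower) stayed within 1.5 times with DESeq2's size factors (717), masked TMM (685), a CPM filter (700), limma-voom (570), thinned counts (684) and protein-coding genes alone (640). Totals became 1791 (1695 higher) with library totals alone, 1157 (844 higher, 313 lower) with every gene of at least 1 count and 1544 (1135 higher, 409 lower) with DESeq2. They were 1577 (1032 higher, 545 lower) with sample weights, 1259 (1147 higher) with the deposited TMM-normalised values, 1670 (1639 higher, 31 lower) with the deposited TPM, 1785 (1691 higher) with the deposited CPM and its offset, and 1895 (1794 higher) with the deposited CPM plus 1. The cause was not tested, except that the scalings without edgeR's factors moved the median of all genes up by 0.27 with library totals, 0.14 with the deposited TMM-normalised values, 0.26 with TPM, 0.26 with CPM plus 1 and 0.28 with the CPM offset. With the muscle score as a covariate, 6 genes passed (2 higher, 4 lower), 3 of them shared with the 679, and 17 lists passed (15 higher, 2 lower), 15 of them shared with the 23. Leaving out 1 library gave 63 to 1382 genes, 47 to 763 higher and 16 to 619 lower, with 63 without wild-type replicate 3 (57 shared with the 679), 328 without wild-type replicate 2, 1382 without wild-type replicate 1, 401 without Tsk replicate 5 and 389 without Tsk replicate 6. Fewer samples were fitted in these, and 91 genes were lower without Tsk replicate 4. Of the 73 named genes past the threshold besides Fbn1, 61, 48 and 17 stayed past it without wild-type replicates 1, 2 and 3, and 63, 59 and 49 without Tsk replicates 4, 5 and 6. Krt24 passed in 0 of these 6 fits, and Thy1, Myh11, Mmp14, Timp2, Fbn2, Sprr1a, Krt71 and Pinlyp in 1 each. None of the 73 changed sign under any alternative. The list tests went from 23 to 0 passing (0 higher, 0 lower) with an estimated correlation and with fry. The sebaceous gland list changed its test direction with the muscle covariate, at a mean of 0.0060. Genes named as values without passing could change sign, and the cause was not tested. With library totals alone, the values that changed sign were Cox8b 0.057, Atp5b 0.075, Atp5a1 0.10, Ighm 0.098, Cd3d 0.10, Tef 0.15, Kdm5d 0.14, Krt1 0.016 and Hspa1b 0.24. With limma-trend on the log2 of the deposited CPM plus 1, the values that changed sign were Ivl 0.0045, Top2a 0.0054, Cox8b 0.070, Atp5b 0.060, Atp5a1 0.098, Ighm 0.083, Cd3d 0.059, Tef 0.15, Kdm5d 0.15 and Hspa1b 0.23. With limma-trend on the deposited CPM with its 0.0001 offset, the values that changed sign were Ivl 0.0059, Top2a 0.0088, Cxcr2 0.0018, Cox8b 0.071, Atp5b 0.060, Atp5a1 0.098, Ighm 0.086, Cd3d 0.066, Tef 0.15, Kdm5d 0.16 and Hspa1b 0.23. With the deposited TMM-normalised values, the values that changed sign were Tef 0.018, Kdm5d 0.027 and Hspa1b 0.096. With the deposited TPM, the values that changed sign were Cilp 0.012, Mki67 0.016, Cox7a1 0.17, Ms4a1 0.022, Top2a 0.094, Ddx3y 0.14, Cxcr2 0.094, Cox8b 0.29, Atp5b 0.28, Atp5a1 0.32, Ighm 0.26, Cd3d 0.15, Tef 0.34, Kdm5d 0.16, Itgb4 0.028, Itga6 0.14, Ivl 0.20, Krt1 0.20 and Hspa1b 0.44. With sample weights, the value that changed sign was Calr -0.035. With the muscle score as a covariate, the values that changed sign were Nr4a1 0.30, Cilp 0.54, Cox7a1 0.63, Cox8b 0.67, Atp5b 0.45, Atp5a1 0.54, Ighm 0.028, Tef 0.052, Hspa1b 0.19, Mitf -0.099 and Hmgcs1 -0.049. When 1 library was left out, the ranges that crossed 0 were Cox8b -0.52 to 0.022, Atp5a1 -0.42 to 0.029, Ighm -0.31 to 0.024, Hspa1b -0.21 to 0.10, Mitf -0.062 to 0.11, Krt84 -1.15 to 0.18, Ifi27 -0.22 to 0.52 and Calr -0.013 to 0.070. Ranges that moved by over 1.5 times without crossing 0 were Nr4a1 -1.30 to -0.65, Csf3r -1.35 to -0.36, Cilp -0.91 to -0.31, Mki67 -0.73 to -0.16, Cox7a1 -0.65 to -0.058, Top2a -0.54 to -0.038, Ddx3y -0.39 to -0.18, Atp5b -0.44 to -0.024, Cd3d -0.47 to -0.020, Tef -0.21 to -0.039, Kdm5d -0.22 to -0.045, Hsp90b1 0.061 to 0.20, Per1 0.059 to 0.17, Hmgcs1 0.068 to 0.34, Ccn2 0.068 to 0.35, Acta2 0.19 to 0.53, Trdc 0.098 to 0.56, Bgn 0.20 to 0.72, Tgfb1 0.27 to 0.59, Gata2 0.19 to 0.77, Selenbp1 0.27 to 0.67, Krt79 0.23 to 0.96, Hbb-bs 0.20 to 1.81, Lyz2 0.44 to 1.15, Hba-a2 0.59 to 1.73, Cfd 1.60 to 2.91, Adipoq 1.72 to 3.57, Scd1 1.21 to 3.69, Krt71 3.18 to 5.83, Krt5 -0.92 to -0.34, Krt14 -1.09 to -0.37, Itgb4 -0.65 to -0.26, Itga6 -0.46 to -0.078, Ivl -0.46 to -0.072 and Krt1 -0.64 to -0.013. Myh4, Nr4a1, Aldoa, Pkm, Cilp and Dct passed without wild-type replicate 1, and Adipoq without Tsk replicates 5 and 6.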

Other observations

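The lists in this part, and all the tests of explanations in it, were chosen after the results were seen. Genes of developing or denervated muscle had 11 of 15 tested members lower in Tsk skin, with a median log2 fold change of -1.61 that ran from -1.78 to -1.49 when 1 library was left out. Chrng, the fetal acetylcholine receptor subunit, was the lowest at -3.78 ± 0.72 (SE), and Tnnt2, Actc1, Chrnd and Chrna1 stood at -1.61, -1.77, -1.55 and -1.07. Chrng held 75, 17 and 70 counts in wild type and 10, 2 and 2 in Tsk, so its fold rests on few counts. Because the list was written after these falls were seen, its size set against the fixed skeletal muscle list (median -0.81) is a description, not a test. Markers of fascial and adventitial fibroblasts had 8 of 12 members higher, with a median of 1.28. Pi16 stood at 3.14 ± 0.43, Dpp4 at 2.36 ± 0.20, Anxa3 at 2.03 ± 0.18 and Gfpt2 at 1.93 ± 0.26, while Sema3c (0.12) and Cd55 (-0.16) did not pass. The list shares Wnt2 with the Wnt list, Cd55 with the complement list and Cd34 with the hair follicle stem cell list.

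Among 15 retinoid genes, 3 were higher, the retinaldehyde dehydrogenases Aldh1a3 (3.34 ± 0.33) and Aldh1a2 (3.03 ± 0.57) and the retinoid-responsive gene Rarres2 (1.71 ± 0.28). Aldh1a1 stood at -0.51 ± 0.26 and the retinoic acid target Rarb at -0.017 ± 0.22, neither past the threshold. Aldh1a2 was at 0.460 ± 0.467 CPM in wild type, so its fold rests on few counts.

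The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05, and 1 of them, the real one with 679 genes, gave that many, while the highest of the others gave 0. Of the 679 genes, 670 lay over 20 Mb from Fbn1 or on another chromosome. The tests held 320 other genes within 20 Mb, so most of the 679 had to lie elsewhere. Changed genes were not concentrated near Fbn1, at 2.5% within 20 Mb against 3.41% elsewhere (Fisher's exact test, two-sided p = 0.439). These shares argue against altered expression of the genes near Fbn1 alone, but a linked gene that acts on genes elsewhere stays open. A smaller share of skeletal muscle in the Tsk pieces may contribute and cannot be told apart from the genotype, because that share was lower in the Tsk libraries. As the whole cause, it would raise the markers of every other cell type alike. The adipocyte score minus the epidermis score moved by 1.15 ± 0.76 (SE) with the groups overlapping. This pair is too variable to decide that question. Wild-type replicate 1 had a muscle score of 11.66, inside the Tsk range of 11.44 to 11.72. Its Fbn1 stood at 260 CPM, against 1447 to 2049 in Tsk. With the muscle score as a covariate Fbn1 rose by 2.74 (edgeR adjusted p = 0.0357). These values argue against muscle share as the whole cause for Fbn1. On the first principal component that replicate stood at -27.6, against 27.7 to 42.3 in Tsk, but this rests on 1 library. Of 78 pairs of other cell type lists, 9 separated the groups, where chance gives 10%, and 5 of these moved apart by over 2 SE. With the muscle score as a covariate all 679 kept their direction and the median size went from 1.24 to 1.21. The 679 were picked from these same libraries for a small p, which makes that likely. The median SE rose from 0.21 to 0.31 with 3 residual degrees of freedom, so 6 genes passed. By camera with the preset correlation, on which each list call rests, 15 of the 23 lists still passed.

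The higher Fbn1 count was set against the added length of the Tsk transcript and against more matrix-producing tissue. Exons 17 to 40, taken as the duplicated part from background knowledge, make up 2952 of 11971 bases of the longest annotated transcript. If the samples are heterozygous for that duplication, it could raise the count by at most 1.12-fold at equal allele output. The lower 95% limit of the observed fold was 4.21 by a normal approximation, which gives a narrower interval than the F-test would. Log2 Fbn1 minus the collagen list score rose by 1.77 ± 0.25 (SE) with the groups separated. That score averages collagens with processing genes such as Crtap (0.94 ± 0.13), which can dilute the rise of single collagens. Fbn1 rose by 2.54 ± 0.24 and Col14a1 by 2.14 ± 0.30, while Col1a1 (1.83 ± 0.44) and Col3a1 (1.24 ± 0.38) did not pass. The score therefore cannot decide whether a larger share of collagen-producing cells accounts for the Fbn1 count. That explanation stays open, as does a change in one fibroblast type rich in Fbn1, in the stability of the transcript or in its transcription. The genotype and the strain label that goes with it remain untested explanations.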
